A study of Homo sapiens with 9 samples.

How the data were processed

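Gene expression was measured on 9 Affymetrix whole-transcript arrays, with biotin-labelled cDNA made from 300 ng of total RNA per array, per the labels' protocols. The cells were EA.hy926, an established hybrid line of umbilical vein endothelial cells and the A549 lung carcinoma line. The labels put 3 arrays in each of 3 groups: unexposed cells, cells exposed to 5 nm silver nanoparticles and cells exposed to 100 nm silver nanoparticles. Exposure lasted 6 h at about the LD50, per the labels' protocols; the mass doses are not given in the sources used here. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The series title also names a bronchial epithelial line, which was not analysed here.

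The deposited values are log2 intensities of 53617 probe sets, made by the authors with RMA (background correction, quantile normalization and median polish over the arrays summarised together) in Affymetrix Expression Console 1.3.1, per the submitters' processing notes. The values carry a trace of how that step was run. Array quantiles differed by 0.0044 to 0.0234 on the log2 scale between arrays of the same replicate number and by 0.192 to 0.455 between arrays of different numbers. Exactly equal values were found for 46.9% to 57.6% of probe sets between arrays of the same number, and for at most 0.00373% between arrays of different numbers. In 41.2% to 43.9% of probe sets all 3 arrays of a number held 1 identical value. This is the pattern that RMA leaves when 3 arrays at a time are normalized and summarised, which the submitters' processing notes do not mention. The tests that give the reported counts hold no term for these sets, so offsets between sets stay in their residual spread. Differences within each set and fits with the replicate number as a block are given beside them. A median polish over 3 arrays can set small differences to exactly 0, so differences within a set are exact 0 for many genes, and small true differences may be hidden there. If so, levels compared across sets carry the difference between the separate normalizations, and differences within a set do not.

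Of the probe sets, 16098 had 1 gene symbol in the platform annotation, 0 had several and 37519 (70.0%) had none here. Symbols were updated through the Entrez identifier, which matched for all 16098. They covered 14884 genes, 779 of them with more than 1 probe set, and the probe set with the highest mean over the 9 arrays stood for the gene. A gene was tested if its log2 value reached 5 on at least 3 arrays, which left 12155 genes. The genome build is not given in the sources used here, so no coordinates are printed. Each array had 10764 to 11944 genes at or above a log2 value of 5. With 3 arrays per group, the spread between arrays limits the precision, and each difference is given with its interval or its values per set.

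Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated t for each comparison and a moderated F over the groups), on all 9 arrays with group means and 6 residual degrees of freedom with Benjamini-Hochberg adjusted p under 0.05. The comparisons were 5 nm minus control, 100 nm minus control and 5 nm minus 100 nm. The last is also the difference of the other 2, which share the same 3 control arrays. The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Named genes were the 10 largest rises and falls among genes past the threshold whose exposed arrays lay outside the control range, up to 4 members of each list that passed (or 2 members given as values where none passed), the 5 largest differences each way between the particle sizes, and a fixed set of stress and reference genes, where they were tested. DNAJB1, CHAC1, IL6 and ACTB had no named probe set and were not analysed here. A second set of names was chosen after the values were seen: genes past the threshold with the replicate number as a block, and genes at least doubled, or lower by over 0.5, in all 3 sets. Other genes named outside these rules are said to be so where they appear.

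The replicate numbers in the labels were checked for pairing. Deviations from the group means correlated at r = 0.762 to 0.967 between arrays of the same number in different groups (9 pairs) and at r = -0.582 to -0.265 between arrays of different numbers (18 pairs), and 9 of 9 arrays correlated best with their own number. The numbers therefore pair the arrays, whether through shared handling or through the apparent separate normalization. The fit with the number as a block left 4 residual degrees of freedom and is given beside results it changes.

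For 28 gene lists, 23 had at least 5 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists; camera with an estimated correlation and fry were run as alternatives. Of 552 list symbols, 6 were updated to a current symbol. Members without a named probe set or under the floor were not tested, so a call covers the tested members only. These were 15 of 28 heat shock genes, 14 of 28 NRF2 targets, 10 of 24 p53 targets and 27 of 33 mitosis genes. The lists not tested were zinc and copper transport, fibroblast and smooth muscle markers (3 tested members each), the proteasome, small nucleolar RNAs and replication-dependent histones (0 tested members each). Other alternatives were no filter, a floor of 6, a second quantile normalization, median centring, eBayes with trend and robust, arrayWeights, a fit to only the 2 groups compared, the mean of a gene's probe sets, all probe sets separately, each array left out in turn, and a threshold of 0.01. Settings added after the data were seen paired the block with trend and robust, with the 2 groups compared, with an estimated correlation or with fry. The within-set counts were added then too.

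The steps were tested on simulated data for the 5 nm comparison, 5 sets of arrays on 12155 genes, built from the mean of each real replicate set and the spread of the fit with the block. Without the block, 85.2% of genes changed by a log2 difference of 2 were recovered, and 4.4% of those changed by 1. With the block, 97.2% and 91.2% were recovered. Among 59675 simulated values of unchanged genes, 0 were called without the block and 82 with it. A list of genes shifted by 0.5 was called in 5 of 5 sets in both fits, and 0 of 95 lists left alone were called. Each simulated change was equal in every replicate set, whereas real 5 nm differences varied between replicate sets. Their median SD across sets was 0.446 for absolute mean differences of at least 0.5 and 0.0353 for those under 0.1. The shares recovered therefore hold only for changes equal in every set. The simulation has no exact ties, and its noise was drawn independently for each gene. In the real lists the estimated correlation without the block ran from 0.0259 (coagulation) to 0.826 (DNA replication). The simulation therefore cannot show how often camera calls unshifted lists of correlated genes. Offsets between sets can raise those estimates. Adding the block lowered the estimate from 0.535 to 0.000689 for zinc-finger genes and from 0.613 to -0.0112 for ribosomal proteins. For mitosis genes it was 0.823 and then 0.818, and for the integrated stress response it rose from 0.437 to 0.485. A call lost with an estimated correlation therefore need not come from correlated regulation of the members. HSPA1A and HSPA1B are near-identical copies and metallothionein genes resemble each other, so probes can pick up more than 1 of them and their values are uncertain as to the single gene.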

Results

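Expression was compared in EA.hy926 cells, an established human endothelial hybrid line, on 3 unexposed arrays, 3 arrays of cells exposed for 6 h to 5 nm silver nanoparticles and 3 arrays of cells exposed to 100 nm silver nanoparticles. Both particles were used at about their LD50. The series title asks about interleukin-11 and stress genes. Median log2 intensities of the arrays were 5.15 to 5.64, and 12155 named genes were tested.

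The first question was which genes differed after 5 nm particles. The largest measured rise was in MT1G, a metallothionein that binds metal ions, from a log2 intensity of 4.72 ± 0.61 (SD, n = 3) in controls to 10.16 ± 0.75 (SD, n = 3), a log2 difference of 5.44 (95% interval 4.55 to 6.33, 43.5-fold). That control level lies under the floor of 5 used for testing, where intensity need not follow the amount of RNA, so the size of the rise is uncertain. HMOX1, the inducible heme oxygenase, rose from 8.27 ± 0.39 to 11.88 ± 0.30 (SD, n = 3 each), a difference of 3.61 or 12.2-fold. IL11, a cytokine of the interleukin-6 family, rose by 3.21 (9.24-fold), MMP10, a secreted matrix metalloproteinase, by 2.92, and CXCL8, a neutrophil chemokine, by 2.76 (6.77-fold). HSPA6, an inducible HSP70, rose by 2.39, KDM6B, a histone demethylase, by 2.02, and BAG3, a co-chaperone, by 1.83. The noncoding RNA LINC00622 rose by 3.54, of uncertain size for the same reason (control mean 4.78).

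These 9 genes were all higher and none was lower at the threshold in limma with Benjamini-Hochberg adjustment. Adjusted p (limma, Benjamini-Hochberg) was 0.00069 for MT1G, 0.000704 for HMOX1, 0.00278 for CXCL8, 0.00421 for MMP10, 0.00555 for IL11 and for HSPA6, 0.0365 for LINC00622, and 0.0453 for KDM6B and for BAG3. At an unadjusted p under 0.05, 201 genes passed without the replicate block (165 higher, 36 lower), where 608 would pass by chance if p-values were uniform. The fit with the replicate number as a block gave 1739 genes at that limit (666 higher, 1073 lower). After adjustment 79 genes passed with the block (36 higher, 43 lower). Of these, 4 were among the 9: HMOX1 (adjusted p = 0.0202 in limma), MT1G (0.0285), MMP10 (0.034) and CXCL8 (0.0426). With the block fitted to only the 2 groups compared, which leaves 2 residual degrees of freedom, 0 genes passed. The other 5 no longer passed with the block: BAG3 (0.0514), HSPA6 (0.0671), IL11 (0.0712), KDM6B (0.107) and LINC00622 (0.133). Without the 5 nm array of replicate 3, 15 genes passed and not 9. The count of 79 became 11, 10 and 2 without the control array of replicate 1, 2 or 3, then 131, 326 and 446 without the 5 nm arrays and 11, 13 and 11 without the 100 nm arrays in the same order. Over 18 alternatives, the adjusted p in limma ranged from 0.000148 to 0.0285 for MT1G, 0.00026 to 0.0267 for HMOX1, 0.00133 to 0.0437 for CXCL8, 0.00119 to 0.07 for MMP10, 0.00258 to 0.0712 for IL11, 0.00119 to 0.0671 for HSPA6, 0.0105 to 0.234 for LINC00622, 0.0269 to 0.325 for KDM6B and 0.00743 to 0.325 for BAG3.

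**Figure D1:**
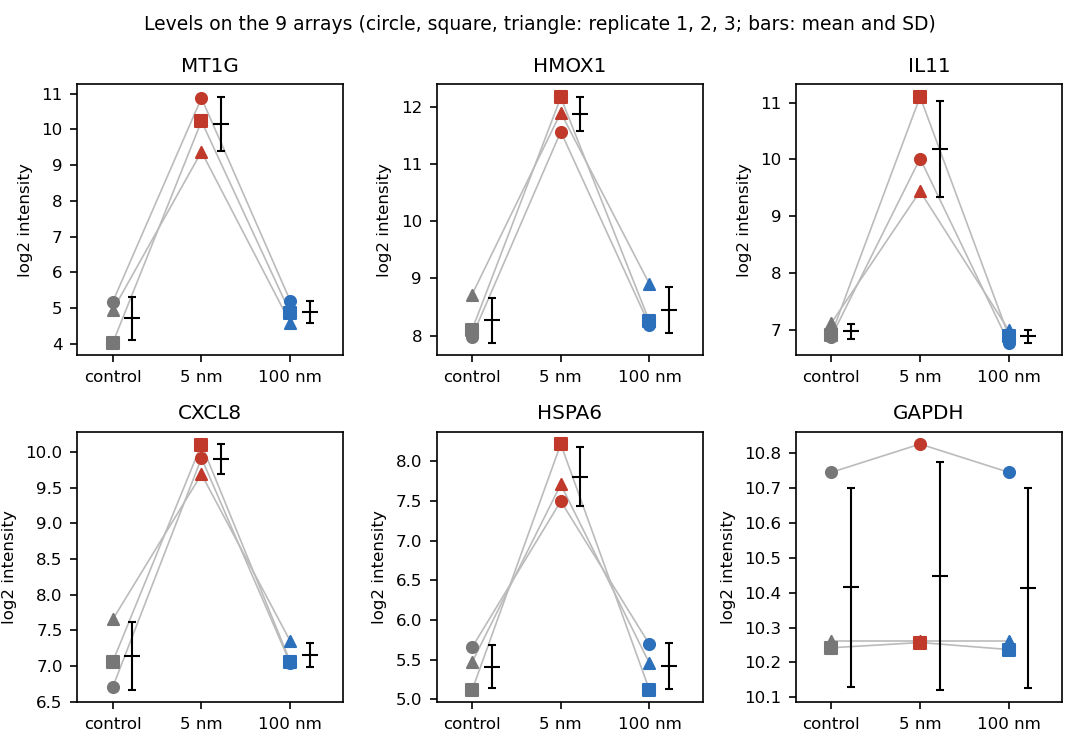
Log2 intensity of MT1G, HMOX1, IL11, CXCL8, HSPA6 and GAPDH on the 9 arrays by group, with the mean and SD of 3 arrays beside the points and lines joining arrays of 1 replicate number. HMOX1 lies at 8.27 in controls, 11.88 with 5 nm and 8.45 with 100 nm particles on average, while GAPDH averages 10.42, 10.45 and 10.41.

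Because the values carry the pattern of arrays normalized in sets, the difference from the control of the same number was also taken within each set. In all 3 sets 27 genes were at least doubled by 5 nm particles and none was halved. HMOX1 was higher by 3.58, 4.06 and 3.18 in replicates 1, 2 and 3, IL11 by 3.13, 4.18 and 2.31, and CXCL8 by 3.21, 3.04 and 2.03. Genes in this set that did not pass in limma without the block, and are given as values, included DDIT3, the stress factor CHOP (2.83, adjusted p = 0.266 in limma), SESN2, a stress-induced regulator of growth signalling (2.30, adjusted p = 0.0603), and INSIG1, a brake on sterol synthesis (1.67, adjusted p = 0.134). HSPA1A and HSPA1B, 2 inducible HSP70 genes, were higher by 1.75 and 2.06. They did not pass in limma without the block (adjusted p = 0.0603 and 0.0739) and passed with it (0.00271 and 0.0173; over 18 alternatives 0.00271 to 0.346 for HSPA1A and 0.0101 to 0.507 for HSPA1B). Their near-identical sequences leave open which copy was measured.

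**Figure D2:**
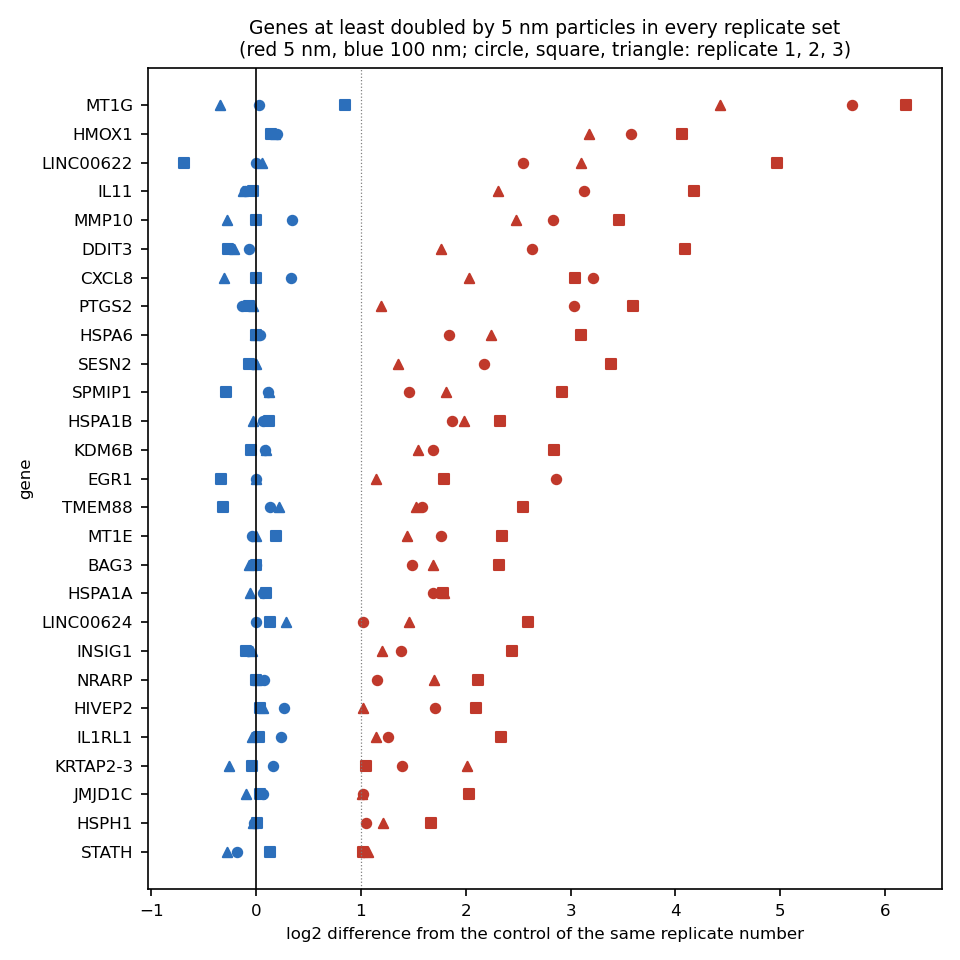
Log2 difference from the control array of the same replicate number for the 27 genes at least doubled by 5 nm particles in every set, with 5 nm values in red and 100 nm values in blue. HMOX1 lies at 3.58, 4.06 and 3.18 with 5 nm particles, and at 0.20, 0.15 and 0.18 with 100 nm particles.

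Heat shock genes moved together with 5 nm particles. All 15 tested members of the heat shock and chaperone list had positive differences, 13 of them in all 3 sets. Of these, 2 passed over all genes and 7 when adjusted over the list alone. The list's camera adjusted p was 2.26e-38, and it kept its call with an estimated correlation (adjusted p = 0.0485). HSPA6 and BAG3 were the members past the threshold over all genes, and with the block they were HSPA1A and HSPA1B instead. Of 7 tested metallothioneins, 6 were positive and 1 passed, MT1G, with 3 passing adjusted over the list alone (camera adjusted p = 6.91e-18 and adjusted p = 0.0485 with an estimated correlation). MT1X was higher by 1.15 without passing (adjusted p = 0.491 in limma), while MT2A, the most widely expressed family member, differed by -0.13. Immediate-early factors and phosphatases, the early response to growth and stress signals, had 18 of 26 members positive and 7 negative, with 0 passing over all genes and 3 adjusted over the list alone. The list, with a median of 0.1 and a mean of 0.324, was called higher by camera (adjusted p = 3.05e-07, and adjusted p = 0.0485 with an estimated correlation). EGR1 (1.93, adjusted p = 1 in limma) and ARC (1.37, adjusted p = 0.446) had its largest differences, and a second, dimmer EGR1 probe set had a difference of 0. Under the block, all 3 lists lost the call in camera with an estimated correlation (adjusted p = 0.22, 0.22 and 0.263). The estimates there were 0.497 for heat shock genes, -0.0989 for metallothioneins and 0.0755 for the immediate-early list. The metallothionein estimate lies below the preset 0.01, so its size does not explain that lost call. What else differs between the settings was not tested.

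Other stress lists were called higher by camera at the preset correlation and lost the call when the correlation was estimated. For NRF2 targets and glutathione genes, the antioxidant response, 12 of 14 members were positive and HMOX1 alone passed, over all genes and over the list alone (adjusted p = 3.59e-14, and adjusted p = 0.0921 with an estimated correlation). With the block 3 members passed: HMOX1, TXNRD1 (0.79, adjusted p = 0.0202 in limma, 0.0202 to 1 over 18 alternatives), which encodes thioredoxin reductase, and GSR, glutathione reductase (0.37, adjusted p = 0.0327), which was chosen after its values were seen. The integrated stress response list had 16 of 18 positive, 0 passing over all genes and 5 adjusted over the list alone (adjusted p = 1.58e-22, and adjusted p = 0.0554 with an estimated correlation); DDIT3 and SESN2 differed most, while GDF15 differed by 0.10 and ATF3 by 1.28 (adjusted p = 0.984). Endoplasmic reticulum chaperones had 11 of 12 positive and 0 passing over all genes or adjusted over the list alone (adjusted p = 3.16e-08, and adjusted p = 0.208 with an estimated correlation), led by SDF2L1 (1.40) and XBP1 (0.91). In the interleukin-6 family list 5 of 7 members were positive, 2 of them in all 3 sets, with a median of 0.061 and a mean of 0.73. IL11 passed, and 2 passed adjusted over the list alone (camera adjusted p = 3.05e-07, and adjusted p = 0.0921 with an estimated correlation). In the inflammatory list 12 of 16 were positive, 5 of them in all 3 sets, with a median of 0.111 and a mean of 0.435. CXCL8 passed, and 2 passed adjusted over the list alone (camera adjusted p = 3.05e-07, and adjusted p = 0.0921 with an estimated correlation).

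Genes of cell division had negative differences with 5 nm particles. All 27 tested mitosis genes were negative, 22 of them in all 3 sets, with a median of -0.52, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 6.91e-18, and adjusted p = 0.208 with an estimated correlation). CCNA2, cyclin A2, differed by -0.89 and MKI67, a proliferation marker, by -0.80. The differences were most negative in replicate 2 (MKI67 -0.64, -1.36 and -0.39 and CCNA2 -0.70, -1.45 and -0.52 in replicates 1, 2 and 3), where 143 genes were halved against 1 and 2 in replicates 1 and 3. With the block 1 member passed over all genes and 17 adjusted over the list alone. The former was PRC1, a spindle midzone protein chosen after its values were seen (-0.20). Of 24 DNA replication genes, 21 were negative (adjusted p = 1.7e-06, and adjusted p = 0.469 with an estimated correlation), among them PCNA (-0.64; -0.49, -1.10 and -0.34 in replicates 1, 2 and 3) and GINS1 (-0.61; -0.44, -1.23 and -0.15), and 0 passed. With the block MCM7, a helicase subunit chosen after its values were seen, passed (-0.33). Of 10 tested p53 targets, from a list of 24, 8 were negative. The camera adjusted p was 0.00115, then 0.394 with an estimated correlation and 0.05 with the block. SESN1 differed by -0.69 (-0.42, -1.27 and -0.38 in replicates 1, 2 and 3), whereas PMAIP1, a pro-death BCL2-family gene, differed by 1.38. PMAIP1 was the member that passed adjusted over the list alone. Of 19 endothelial markers, 13 were negative, with a median of -0.12 (adjusted p = 0.0273, and adjusted p = 0.603 with an estimated correlation); KDR differed by -0.38 and ICAM2 by -0.33, neither passing.

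The remaining lists called by camera were small or divided. Cholesterol genes had a median of -0.0058 and a mean of 0.30 and were called higher (adjusted p = 3.38e-05, and adjusted p = 0.402 with an estimated correlation; adjusted p = 0.48 with the block), through INSIG1 (1.67) and HMGCS1 (1.23), while 8 of 15 members were negative. Hypoxia targets (adjusted p = 0.00508, and adjusted p = 0.516 with an estimated correlation; adjusted p = 0.0783 with the block) were led by VEGFA (1.10), autophagy genes (adjusted p = 0.0126, and adjusted p = 0.603 with an estimated correlation) by MAP1LC3B (0.94), and TGF-beta, BMP and YAP targets (adjusted p = 0.0313, and adjusted p = 0.585 with an estimated correlation; adjusted p = 0.153 with the block) by SKIL (0.78). Over all genes 0 members of these lists passed; adjusted over the list alone INSIG1 and VEGFA did. Lists not called were BCL2 family and death regulators (median 0, mean 0.047, camera adjusted p = 0.527), coagulation (0.187), epithelial markers (0.527), leukocyte markers (0.882), housekeeping genes (0.974, median -0.012 with a test direction of higher), zinc-finger genes (0.3) and ribosomal proteins (0.432), the last called lower with the block (adjusted p = 0.0188, and adjusted p = 0.22 with an estimated correlation). The estimated correlation of ribosomal proteins with the block was -0.0112, below the preset 0.01, so its size does not explain that lost call. GAPDH differed by 0.03. In all, camera called 16 of 23 lists, 12 higher and 4 lower; 3 held with an estimated correlation. With the block camera called 13 lists: p53, cholesterol, hypoxia and TGF-beta, BMP and YAP targets lost their call and ribosomal proteins gained one. Fry called 0 lists without the block and 12 with it, coagulation, epithelial markers and ribosomal proteins among them and the integrated stress response, immediate-early and DNA replication lists not. All 23 lists kept their direction under both other scalings.

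**Figure D3:**
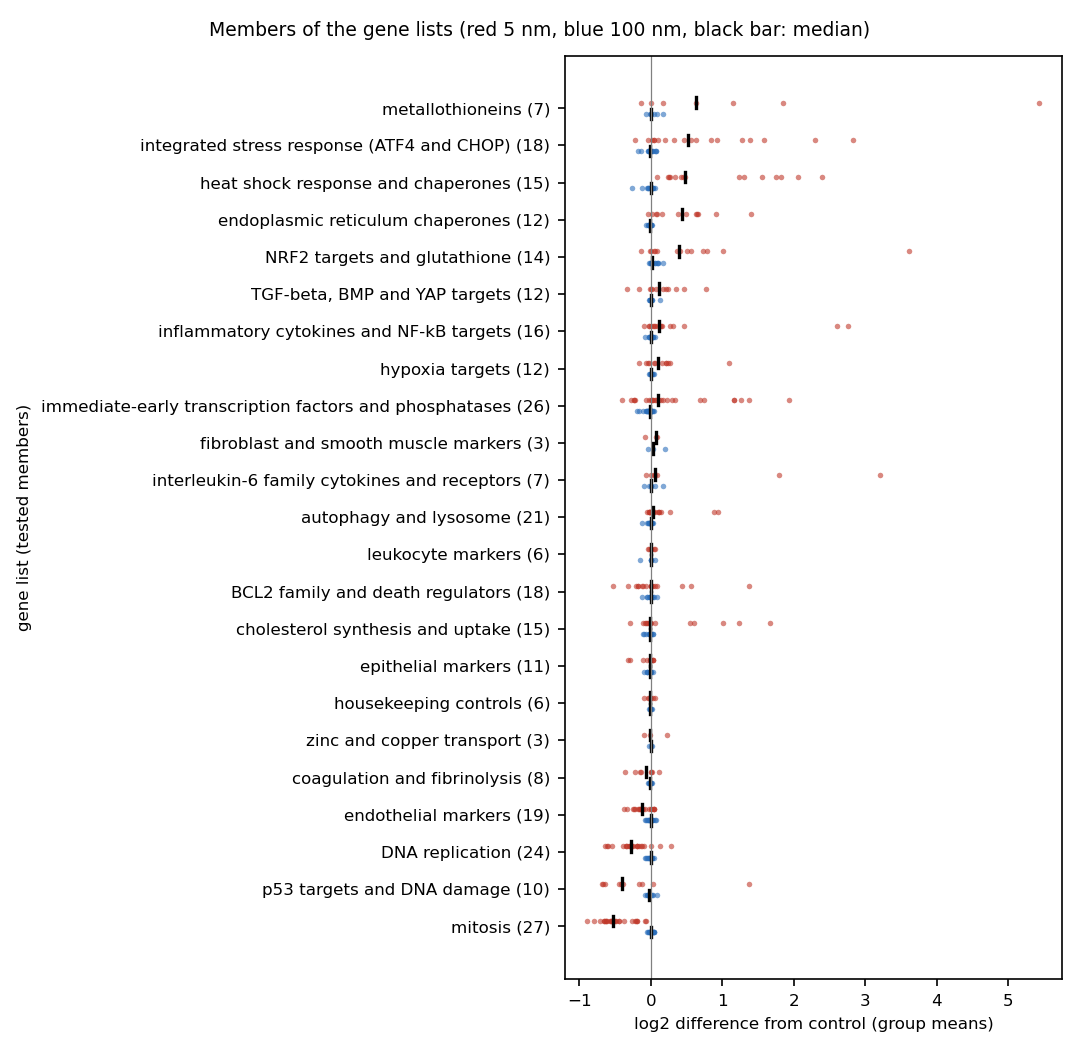
Log2 difference from control of each tested list member with 5 nm particles (red) and 100 nm particles (blue), and the median of each list (black bar), without the 382 zinc-finger genes and the 48 ribosomal protein genes. The mitosis median lies at -0.52 and the heat shock median at 0.48 with 5 nm particles.

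The second question was which genes differed after 100 nm particles. None passed in limma with Benjamini-Hochberg adjustment, with or without the replicate block, and at an unadjusted p under 0.05 there were 0 without the block and 33 with it, against 608 by chance. HMOX1 differed by 0.17 (95% interval -0.46 to 0.81), IL11 by -0.09 (-0.87 to 0.69) and HSPA1A by 0.03 (-0.57 to 0.64). MT1G lay under the floor of 5 in both groups (means 4.72 and 4.90), so its difference is not given. Within sets, HMOX1 was higher by 0.20, 0.15 and 0.18, and no gene was doubled, halved or moved by over 0.5 in all 3 sets. The NRF2 list was the 1 list called, higher, with a median of 0.012 (camera adjusted p = 0.0405, and adjusted p = 0.976 with an estimated correlation; adjusted p = 0.174 with the block). With the block, epithelial markers and ribosomal proteins were called lower instead (adjusted p = 0.0351 each, and adjusted p = 0.348 with an estimated correlation), with medians of -0.015 and -0.0060. Their estimated correlations were -0.0763 and -0.0112, below the preset 0.01, so the size of the estimates does not explain these lost calls. Left-out arrays changed the count of 1 list to 4 (without the control array of replicate 1 or 3 or the 100 nm array of replicate 3), 2 (without the control array of replicate 2 or the 100 nm array of replicate 1 or 2) or 0 (without the 5 nm array of replicate 2). The interval of HMOX1 from the fit without the block, which holds the offsets between sets, reaches a log2 difference of 0.81. From its own spread across the 3 sets (SD 0.0258), a measure chosen after the results were seen, the upper 95% limit was 0.239. The difference of HMOX1 was positive in all 3 sets, so a small rise is not excluded. For the 5 nm comparison, the one simulated, the test recovered 4.4% of genes changed by 1 without the block and 91.2% with it. Those simulated changes were equal in every set, which real ones need not be.

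The third question was whether the 2 particles differed from each other at doses each near its own LD50, so that size and dose are not separated. Of the 9 genes higher with 5 nm particles than in controls, 8 were also higher than with 100 nm particles, and no gene was lower: MT1G (5.27), LINC00622 (3.75), HMOX1 (3.43), IL11 (3.30), MMP10 (2.90), CXCL8 (2.75), HSPA6 (2.38) and BAG3 (1.85). The 100 nm means of MT1G (4.90) and LINC00622 (4.57) lie under the floor of 5, so the sizes of these differences and their order are uncertain. KDM6B did not pass (1.98, adjusted p = 0.0551 in limma, 0.0293 to 0.301 over 18 alternatives). With the block MT1G (adjusted p = 0.0314 in limma), HMOX1 (0.0241), MMP10 (0.0389) and CXCL8 (0.0454) passed, and LINC00622 (0.122), IL11 (0.0685), HSPA6 (0.0685) and BAG3 (0.0538) did not. With the block on only the 2 groups compared 0 genes passed. Over 18 alternatives the adjusted p in limma ranged from 0.000195 to 0.0314 for MT1G, 0.000441 to 0.032 for HMOX1, 0.000939 to 0.0702 for MMP10, 0.00105 to 0.0457 for CXCL8, 0.00699 to 0.122 for LINC00622, 0.00195 to 0.0702 for IL11, 0.00105 to 0.0685 for HSPA6 and 0.0068 to 0.301 for BAG3. At an unadjusted p under 0.05, 207 genes passed without the block and 1738 with it, against 608 by chance. After adjustment 75 genes passed with the block (35 higher, 40 lower), of which 72 were among the 79 of the control comparison. Without the 5 nm array of replicate 3 the count without the block was 19. In the order used above, the count of 75 became 9, 12, 10, 131, 330, 449, 10, 14 and 7 when 1 array was left out. The F-test over the 3 groups called 7 genes, all among the 9, and 36 with the block, of which HMOX1 and MT1G were among the 7. Camera called 15 lists, 11 higher and 4 lower, among them heat shock genes (median 0.52, adjusted p = 6.84e-39, and adjusted p = 0.0408 with an estimated correlation) and mitosis genes (median -0.51, adjusted p = 6.66e-18, and adjusted p = 0.204 with an estimated correlation); 3 held with an estimated correlation and 11 were called with the block, while fry called 0 without the block and 10 with it.

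The differences from control of the 2 particles were nearly unrelated across genes, which are not independent replicates. Their correlation was 0.0741 (0.345, 0.403 and 0.582 without the control array of replicate 1, 2 or 3, and -0.101 without the 100 nm array of replicate 3). With an array left out and no block, the groups hold unequal sets, so offsets between sets enter the differences. Without a control array they enter both differences, so those correlations are not a like measure. The covariance was 0.000804, where unchanged groups simulated against shared controls gave a covariance of 0.00108 (0.000896 to 0.00126 in 100 simulations) and a correlation of 0.494. With noise from the fit with the block, the simulated covariance was 0.0038 and the correlation 0.498. Signs matched for 55.8% of genes, against 66.6% in the simulation. Both simulated groups were unchanged and held no exact ties. The real 5 nm differences spread more over genes (SD per set 0.182 to 0.376) than the 100 nm differences (0.0741 to 0.0878). A larger spread lowers the correlation at the same covariance. The simulated correlation and share of matching signs are therefore not a like measure for the observed ones. Between different sets, which share no array, the covariance was -0.00134 to 0.000761 with a mean of -6.91e-05. Differences of 5 nm particles correlated at r = 0.619 to 0.766 between sets and those of 100 nm particles at -0.0101 to 0.026. As no gene was called with 100 nm particles, an overlap of calls says nothing here. The 3 controls are too few to be split into a pair of groups of at least 2 arrays.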

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

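The splits of the arrays, the comparison of the limits of the particles and the ties among genes without a difference of 0 were tests chosen after the results were seen. The difference between the particles stood out because it was tested directly: 8 genes, MT1G, LINC00622, HMOX1, IL11, MMP10, CXCL8, HSPA6 and BAG3, were higher with 5 nm than with 100 nm particles, 4 of them (MT1G, HMOX1, MMP10 and CXCL8) also with the block, and 0 with the block on only the 2 groups compared. Probe sets without a gene symbol here, which the comparisons of named genes do not use, also held a signal: 3 of 21616 tested were higher with 5 nm particles (limma, all probe sets tested separately) and 0 with 100 nm particles. Of these, probe set 17054328 was higher by 2.93 (adjusted p = 0.0251 in limma, 0.0526 with the block) and 16751438 by 2.76 (0.0251, 0.1 with the block), both chosen after their values were seen. In all 3 sets 39 such probe sets were at least doubled and 4 halved with 5 nm particles, and 2 were doubled and 2 halved with 100 nm particles.

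More genes passed with 5 nm than with 100 nm particles (9 against 0). Imprecise 100 nm differences that hid a rise of the 5 nm size are argued against for the genes other than LINC00622. Limits were taken from each gene's own spread across sets. The upper 95% limit with 100 nm particles lay below the lower limit with 5 nm particles for 8 of the 9 genes. The gap was narrowest for KDM6B (-0.0175 between the limits). For LINC00622 the limits overlapped (0.427) because its 5 nm interval was wide (SD 1.27, lower limit 0.397). Its upper 100 nm limit was 0.824, below its 5 nm difference of 3.54. Its control and 100 nm means lie under the floor of 5, so the explanation stays open for LINC00622, as it does for smaller rises. Arrays of cells that did not respond at all (unexposed or mislabelled) may also lie behind the 100 nm group. Genes at least doubled in the other 2 sets had median 100 nm differences of 0.029, 0 and -0.021 in the held-out set, at percentiles 100, 49.96 and 0 of matched random lists, so the sets disagreed, and the random limits were all 0 because of exact ties. Particle size, the unknown mass dose and a weaker response at 6 h cannot be told apart in this design and were not tested.

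With the block, 65 of the 79 genes had differences under 0.5, and exact ties between arrays, which shrink the residual spread, could have helped them pass. In the planned test, control and 100 nm values were tied in all 3 sets for 13.8% of these genes and 30.3% of the other 12090, an odds ratio of 0.369 (95% interval 0.16 to 0.753, Fisher's exact p = 0.00274), opposite to that explanation. That comparison was poorly chosen, since 9089 of the genes had a 5 nm difference of exactly 0 in some set and 0 of them passed. Among the 3066 others the odds ratio was 2.56 (1.1 to 5.33, Fisher's exact p = 0.0152), though 56 of the 65 genes were not tied in this way and ties in at least 1 set gave 1.15 (0.661 to 2.07). The question stays open, and no biological explanation was tested.

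The 5 nm differences were larger in replicate 2 than in replicates 1 and 3, with an SD over genes of 0.376 against 0.213 and 0.182. A 5 nm array of replicate 2 that differs in all genes may explain this. The SD was 1.77 times as large among genes that responded in the other sets and 1.93 times among those that did not, a ratio of 0.914 (bootstrap 95% interval 0.752 to 1.11). The genes were chosen by the other 2 sets, so genes that responded weakly in replicates 1 and 3 could count as not responding for replicate 2. The ratio therefore cannot separate such an array from a stronger response. Among responders, the median difference in the direction of the other sets was 1.67 in replicate 2, 0.71 in replicate 1 and 0.422 in replicate 3. A stronger response of that sample together with broader effects on other genes stays open and was not tested.

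For 5 nm particles against control, 1 of the 10 splits of the 6 arrays, the real one, gave as many as 9 genes, and the highest other gave 0. For 5 nm against 100 nm particles 1 of 10 gave as many as 8, and the highest other 0; for 100 nm against control all 10 gave 0, the real value, as did the highest other. These splits are too few for a share under 0.05. The real split and 3 others part all 3 pairs of replicate numbers, and the others part 1. For the F-test over the groups, 12 of 100 drawn splits (of 280 possible) gave as many genes as the real 7, so chance is not excluded by it. The highest other split gave 7548 genes and largely followed the replicate numbers (7 arrays carried the most common number of their group), a structure of the samples; with the block the real count was 36. Among the 11 drawn splits with 1 array of each number per group, the real one included, 1 other gave as many (7). Whether that split kept the 5 nm arrays together was not checked. The rest of the splits with as many genes spread the numbers unevenly over the groups. All others with as many genes had a median of 2182, so the 12 of 100 largely reflect the replicate numbers and do not measure chance alone.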

How the results depend on the processing

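The fits that join the block with trend and robust, with the 2 groups compared, with an estimated correlation or with fry, and the left-out arrays in the fit with the block, were tests chosen after the data were seen, as was the rule that compares the correlation of the 2 responses with its spread over sets. Genes called with 100 nm particles stayed at 0 in all unblocked alternatives and in the blocked fits on all arrays; with an array left out of the blocked fit they were 0 to 1 (1 without the control or the 100 nm array of replicate 2). Genes at least doubled in all 3 sets numbered 24 to 28 over 5 alternatives, against 27. Named genes gave 147 values and 2636 alternatives, of which 2551 kept direction and side of the threshold, 51 lost the call, 34 gained it and 0 changed direction. Per array 72.3% to 80.2% of genes reached the floor of 5, and genes that did not reach it on at least 3 arrays were not tested in the reported counts.

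Genes called for 5 nm against control (9), for 5 nm against 100 nm (8) and by the F-test (7) numbered 15, 15 and 15 with a floor of 6, 19, 17 and 17 with quantile normalization again, 4, 4 and 3 with each array centred on its median, 79, 75 and 36 with the replicate block, and 54, 30 and 16 with the replicate block with trend and robust. For 5 nm against 100 nm and the F-test they were 13 and 12 with eBayes with trend and robust, and 13 and 13 with arrayWeights. With the replicate block and only the 2 groups compared, both comparisons gave 0, with 2 residual degrees of freedom. Of these, at least doubled were 15 and 15 (floor of 6), 17 and 17 (quantile normalization), 4 and 4 (median), 13 for 5 nm against 100 nm with trend and robust and with arrayWeights, 4 there with the replicate block with trend and robust, and 0 and 0 with the block on 2 groups. With each array left out, the counts and those at least doubled ranged from 6 to 15 for 5 nm, from 6 to 19 for 5 nm against 100 nm and from 6 to 9 for the F-test; the highest values came without the 5 nm array of replicate 3. With the block they ranged from 2 to 446 (5 nm) and from 7 to 449 (5 nm against 100 nm).

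Lists called for 5 nm against control (16) and for 5 nm against 100 nm (15) fell to 3 and 3 with camera at an estimated correlation, 0 and 0 with fry, and 0 and 0 with the replicate block and an estimated correlation, while the replicate block with fry gave 12 and 10; with an array left out they were 12 to 16 in both. For 100 nm against control the 1 list became 0 with no filter, with arrays centred on their median, with trend and robust, with arrayWeights, with an estimated correlation, with fry, with the block and an estimated correlation and with the replicate block and fry, 2 with the replicate block, and 0 to 4 with an array left out, as listed in the report. The correlation of the 2 responses was -0.101 to 0.582 with an array left out. Those fits hold no block and unequal sets per group, so offsets between sets enter this range. The cause of these changes was not tested.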

Other observations

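The test of the Jumonji family was chosen before its result, although values of some members had been seen, and the genes of the first paragraph were chosen after their values were seen. Genes outside the lists' named members also had large 5 nm differences. PTGS2, the inducible prostaglandin synthase, was higher by 2.61 in the group means without passing (adjusted p = 0.36 in limma), LIF, an interleukin-6 family cytokine, by 1.79 (0.227), and MT1E by 1.85 (0.0666). Higher in all 3 sets by over 0.5 were 99 genes and lower by over 0.5 were 18, none of the latter past the threshold without the block. The most negative mean differences among the 18 were those of SIM1, a transcription factor (-1.23), and EVI2B, a membrane protein (-1.13). With the block, 43 genes passed as lower, with a median of -0.27 and a range of -0.66 to -0.074; CDKN3, a cell cycle phosphatase (-0.58), and GDF6, a growth factor of the BMP family (-0.56), were among them.

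KDM6B passed with 5 nm particles, and 2 other Jumonji-domain genes, KDM7A (2.11) and JMJD1C (1.35), had large differences, so the whole family may have been higher. The 25 tested members had a median of 0.045, at percentile 99.84 of matched random lists. Without KDM6B, KDM7A and JMJD1C the other 22 had a median of 0, at percentile 82.8, inside the random limits of -0.0923 to 0.0065. Of these 22 genes, 10 were positive and 10 negative, and the largest difference was 0.61 (JMJD6). The genes left out were the highest of the family, which lowers the median of the rest, while the random lists lost no genes. The test therefore cannot exclude a smaller rise of the other members.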
